A study of Homo sapiens with 324 samples.

How the data were processed

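Single cells of the established human prostate cancer lines DU145 and PC3 were sequenced in a docetaxel-sensitive and a docetaxel-resistant state. Per the labels, cells were captured on a Fluidigm C1, cDNA was made with SMART-seq v4 and libraries with Nextera XT, sensitive cells were kept in 0.1% DMSO and resistant cells in 10 nM docetaxel. There are 324 cells, 72 in each DU145 group and 90 in each PC3 group. The deposited files hold whole-number counts of reads per gene, 1 file per cell, which the authors made before deposit without normalization as far as the values show. Per the submitters' processing notes Bowtie and hg38 were used. Their versions and roles, the counting tool, the annotation and the strand setting are not given in the sources used here. Each file lists 60554 genes by versioned Ensembl identifier and symbol. Of these, 93.4% were matched to GENCODE release 44 by identifier without version, and they hold 99.9% of the reads. Coordinates are those of that release on GRCh38, the build hg38 names. Raw reads were not analysed here.

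A cell was used if it had at least 50000 counted reads and 1000 detected genes, which left out 1 sensitive DU145 and 1 resistant PC3 cell. No limit was set on mitochondrial reads. Of the cells used, 8 were over 25% mitochondrial reads, among them PC3_Res cell 4 at 95.1% of 2727686 reads. Leaving out cells over 25% was among the alternative cell filters. The cells used had from 53570 to 5681782 reads, with medians of 2992454 in sensitive DU145, 2822510.5 in resistant DU145, 1699278 in sensitive PC3 and 2062449 in resistant PC3. Summed over cells the groups hold 189426828, 199472630, 145778474 and 182954343 reads. There are no molecule barcodes, so exact Poisson intervals on summed reads and exact binomial intervals on shares of cells cover counting error only, and amplification and culture differences come on top. Counts were summed per group, because the labels name no separate cultures and cells of a culture are not replicates. The replicate numbers in the labels number cells and pair nothing.

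The 4 sums were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3, and log2 ratios of resistant over sensitive took a prior count of 2. A gene met the level rule with at least 10 CPM in the higher group and a read in at least 25% of its cells. Genes at least 2-fold higher or lower were counted among these, as sizes and not as calls. Where a group had 0 reads, the fold is a bound against 3 reads over that group. Across lines, an edgeR quasi-likelihood test with line as a term ran on the 4 sums (threshold 0.05 after Benjamini-Hochberg adjustment, 1 residual degree of freedom), with DESeq2 1.42.0 as the alternative. The difference between the lines' ratios has no residual degree of freedom and was not tested.

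There were 36 gene lists. A member was measured at 5 CPM or more in either group, and a list's median log2 ratio was set against 10000 random lists of the same size matched on mean level in 20 bins. A median outside their central 95% is said to stand apart in these libraries. Medians of the described lists were the same with members at 0 reads placed at their bound. Lists overlap (G2M phase with spindle checkpoint and mitosis, for example), so they are not independent. Shares of cells were taken after thinning each cell to 1000000 reads without replacement, which kept 59, 69, 77 and 87 cells of sensitive DU145, resistant DU145, sensitive PC3 and resistant PC3. Phases were scored on thinned cells with scanpy 1.11.5 within each line. Position was read as the median of 15 consecutive genes and as runs of genes at least 2-fold apart on 1 side.

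The named genes are NUPR1, ABCB1 and CTNNA1, the 12 highest and 12 lowest ratios per line among genes that met the level rule with an official symbol and a mean of per-cell CPM on the same side, the 10 highest and 10 lowest by the smaller ratio of both lines, the 6 with the largest opposite ratios, and up to 3 members per list with the largest ratios. Of the items the rules name, 1 gene and 1 window of genes are not reported. The lists, this rule, the comparisons with their tests and most alternatives were fixed before the data were examined. Genes named outside the rule were chosen after their values were seen: VPS50 and the other genes that mark the ends of chromosomal regions, the genes absent from a PC3 state, and list members that passed a test.

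Alternatives were other cell filters, DESeq2 size factors or total counts in place of TMM, the mean of per-cell CPM or thinned sums in place of summed counts, leaving out each gene's top cell, odd-numbered or even-numbered cells alone, a prior count of 0.5, and level rules of 50 and 2 CPM or none on the share of cells. Added after the data were seen were a minimum of 9000 detected genes, a minimum of 1000000 reads without thinning, sensitive PC3 cells low or high in ribosomal protein reads alone, ratios less their loess trend on GC content, and the test across lines on genes at 10 CPM or more.

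The log2 ratio, the test across lines and the list rule were tested on simulated data with 50 genes per fold at the depths of the 4 sums. At a dispersion of 0.1 the edgeR test recovered 6, 38, 50 and 50 of 50 genes changed 2, 4, 8 and 16-fold. At the dispersion estimated here, 0.545, it recovered 0 of 50 at 16-fold, so its count of 0 carries little information about single genes. Genes simulated without a change reached 2-fold in 0 cases at a dispersion of 0.01, in 1149 (DU145) and 1227 (PC3) at 0.1 and in 5009 and 5039 at 0.545. The value 0.545 was estimated across lines, so it also holds differences between the lines in their response. The real counts were lower, 848 higher and 983 lower in DU145 and 1895 and 903 in PC3, so 0.545 is too wide for the genes counted. The spread between cultures is not known here, so a count of 2-fold genes without replicates does not separate resistance from differences between cultures. The list rule was simulated at a dispersion of 0.01 alone, where 3 of 40 lists of unchanged genes stood apart and about 2 are due by chance. Windows, runs, shares and phases were not simulated.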

Results

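Docetaxel-resistant sublines of the prostate cancer lines DU145 and PC3, kept in 10 nM docetaxel, were compared with their sensitive counterparts kept in 0.1% DMSO, so resistance and the presence of the drug are not separable here. The comparison asks which transcripts differ between the resistant and sensitive state of each line, and whether the lines share them. ABCB1 encodes the efflux pump that carries taxanes out of cells, and NUPR1, a stress-induced chromatin regulator, is named in the title of the study. Each group is 1 culture as far as the labels tell. Ratios within a line are therefore sizes without a test, and their intervals hold counting error only, without molecule barcodes.

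The lines could be told apart by CTNNA1, which PC3 is known to have lost. It stood at 270.9 and 266.0 CPM in sensitive and resistant DU145 cells and at 0.254 and 0.292 CPM in sensitive and resistant PC3 cells. Of 322 cells, 321 were closest to the mean profile of their own group, the exception being DU145_Res cell 28, which does not test the line of a group. Sensitive PC3 and sensitive DU145 cells differed at least 2-fold in 1532 genes higher and 3036 lower in PC3, among 9600 genes that met the level rule (33.5% higher). Scaling by total counts alone turns that balance, with 2330 higher and 1992 lower (53.9% higher).

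ABCB1 was the gene with the highest ratio in resistant DU145 cells and stood among the genes higher in both lines. Its summed reads were 7 in sensitive and 76111 in resistant DU145 cells, or 0.0421 and 392.6 CPM, a 9323-fold higher level (95% interval 4525 to 23190, log2 ratio 12.85). All 7 sensitive reads came from 1 cell, and over 17 alternatives the log2 ratio ran from 11.06 to 15.07, past the counting interval. In PC3 they were 10 and 4727, or 0.0591 and 25.6 CPM, 432-fold higher (235 to 902, log2 ratio 8.51), with all 10 sensitive reads in 1 cell and a log2 ratio from 7.41 to 11.05 over the alternatives. At an equal depth of 1000000 reads per cell, ABCB1 was read in 0 of 59 sensitive DU145 cells (0%, interval 0 to 6.06%), in 69 of 69 resistant DU145 cells (100%, 94.8 to 100%), in 1 of 77 sensitive PC3 cells (1.30%, 0.0329 to 7.02%) and in 67 of 87 resistant PC3 cells (77%, 66.8 to 85.4%). Without thinning the shares were 1.41%, 100%, 1.11% and 79.8%. The median resistant DU145 cell held 278.1 CPM of ABCB1 and the median resistant PC3 cell 8.15 CPM.

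**Figure D1:**
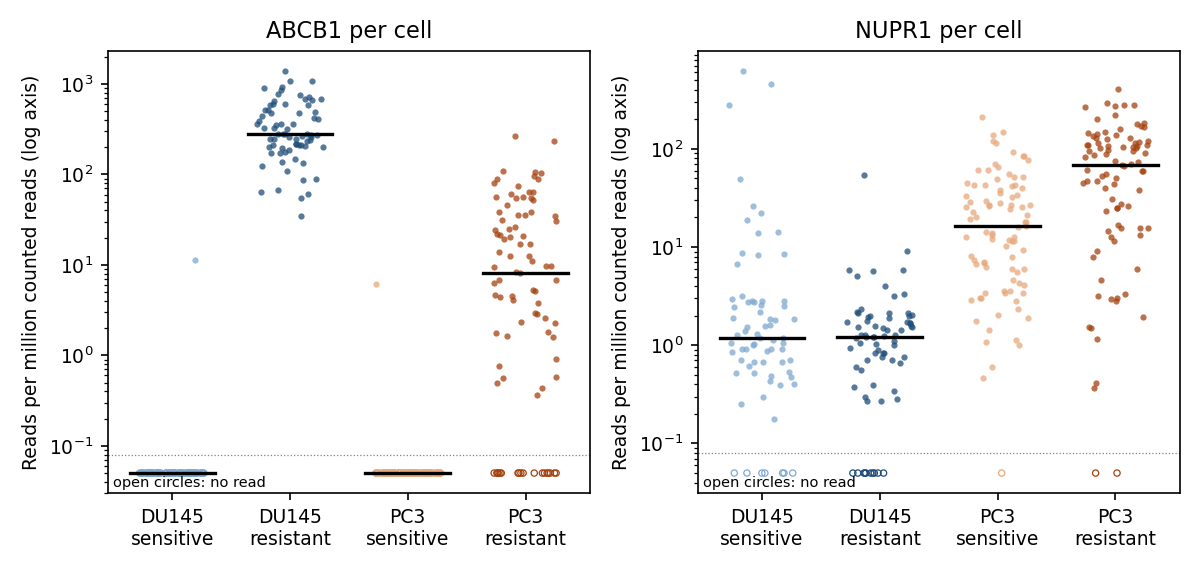
ABCB1 and NUPR1 in single cells of the 4 groups, in CPM of each cell. Cells of a group are not replicates.

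NUPR1 lay in opposite directions in the lines. In PC3 it was 3.23-fold higher in resistant cells (3.12 to 3.34), at 80.8 against 25.1 CPM from 14948 and 4237 reads, log2 ratio 1.69. In DU145 it was 2.60-fold lower (2.33 to 2.90), at 2.47 against 6.41 CPM from 478 and 1066 reads, log2 ratio -1.37, under the level of 10 CPM that the counts of genes required. The DU145 difference rests on few cells: 8 sensitive cells with under 9000 detected genes held 57.8% of the NUPR1 reads of their group and 2.21% of all its reads, and without them the log2 ratio was -0.19. Thinned to 1000000 reads, which leaves out 12 sensitive and 3 resistant cells, it was 0.10, and the same cells without thinning gave -0.17. The median DU145 cell held 1.17 CPM of NUPR1 in the sensitive and 1.22 CPM in the resistant group. At equal depth NUPR1 was read in 38 of 59 sensitive DU145 cells (64.4%, 50.9 to 76.4%), 54 of 69 resistant DU145 cells (78.3%, 66.7 to 87.3%), 74 of 77 sensitive PC3 cells (96.1%, 89 to 99.2%) and 84 of 87 resistant PC3 cells (96.6%, 90.3 to 99.3%), and without thinning in 90.1%, 86.1%, 98.9% and 97.8%.

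In DU145 the genes beside ABCB1 were higher with it. All 12 measured members of the list of ABCB1 neighbours on 7q21.12, ABCB1 itself among them, were at least 2-fold higher, with a median log2 ratio of 3.67 (percentile 100 among random lists). RUNDC3B stood at 1.24 and 31 CPM and ADAM22 at 8.74 and 200.1 CPM in sensitive and resistant cells. A run of 28 consecutive genes from ELAPOR2 to CDK6, on chromosome 7 from 86876906 to 92836573, was at least 2-fold higher, with a median log2 ratio of 2.32 and a lowest of 1.01. The run counts genes at 10 CPM or more, and the next of these, VPS50, was at 0.00. SAMD9, between CDK6 and VPS50 and under that level, stood at 0.0481 and 8.71 CPM. Over that segment, ABCB1 left out, the median cell held 918.2 CPM in sensitive and 9739 CPM in resistant DU145 cells, and all 72 resistant cells lay above the highest sensitive cell. SRI made up much of that sum, with a median of 5166 CPM in resistant and 213.7 CPM in sensitive cells. Its lowest resistant cell, at 2765 CPM, lay above the highest sensitive sum, 1548 CPM, so SRI alone can separate the cells. In PC3 the neighbours had a median log2 ratio of 1.14 (percentile 98.6, 6 of 11 at least 2-fold higher), which no longer stood apart under 2 of 17 alternatives (0.98 in even-numbered cells alone), and the segment held 1418 CPM in the median sensitive and 2214 CPM in the median resistant cell, with 9 of 89 resistant cells above the highest sensitive one. SRI was higher there too, at 292.2 CPM in the median sensitive and 847.3 CPM in the median resistant PC3 cell.

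**Figure D2:**
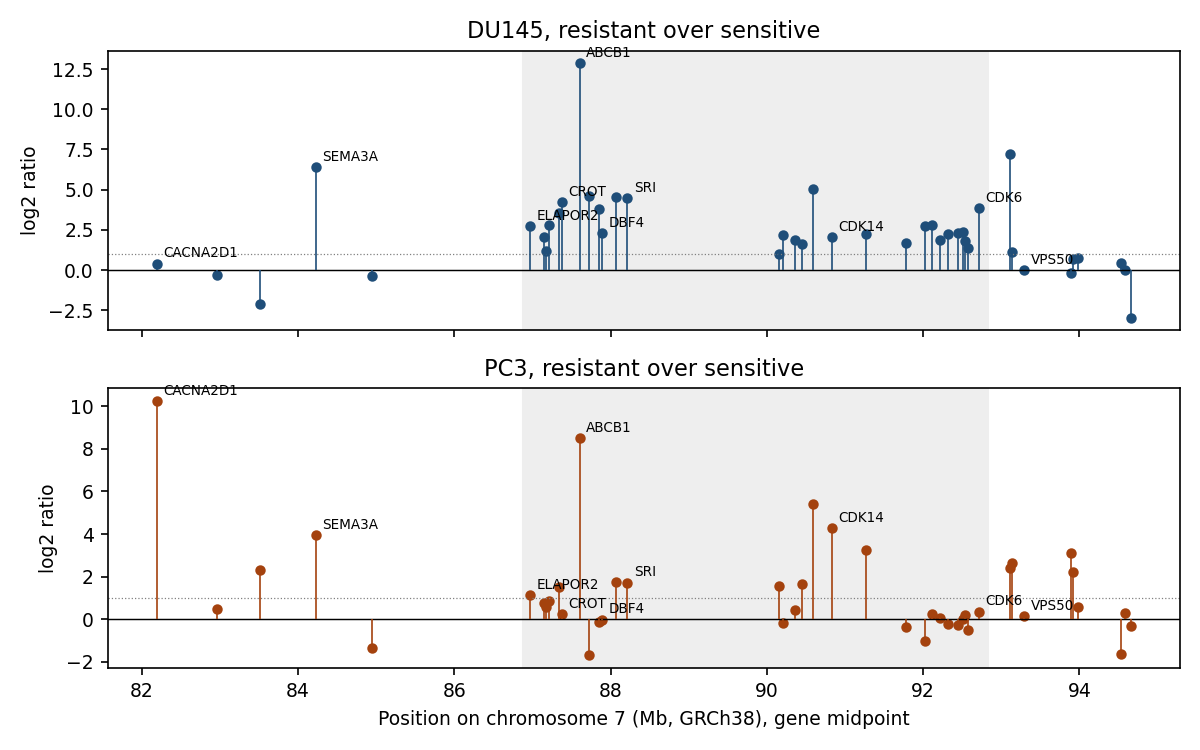
Log2 ratios of genes along 7q21 in DU145 and PC3, resistant over sensitive. The run in DU145 ends at CDK6 among genes at 10 CPM or more.

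In DU145, 848 genes were at least 2-fold higher and 983 at least 2-fold lower in resistant cells, among 9217 genes that met the level rule, so 46.3% of the 2-fold differences were higher. Scaling by total counts alone moves the median log2 ratio by 0.15 and gives 1089 higher and 696 lower, 61% higher. Next to ABCB1 the highest ratios were those of QPCT, at least 908-fold higher against a floor of 3 reads over the group, GSPT2 (at least 777-fold), SMIM6 (at least 628-fold), RAMP1 (226-fold), ALDOC (97.8-fold), EMP1 (83.7-fold), TMEM220 (61.4-fold), SYTL2 (47.8-fold), STC1 (46.7-fold), RTN1 (45.1-fold) and SERPINB7 (43.3-fold). Several of these folds rest on few sensitive cells: over the alternatives the log2 ratio ran from 3.39 to 10.04 for SERPINB7 (60 sensitive reads in 1.41% of cells), from 4.37 to 11.19 for STC1 (169 reads in 2.82%), from 3.99 to 9.31 for ALDOC, from 4.44 to 9.91 for RTN1 and from 6.82 to 10.99 for RAMP1. The lowest were CAVIN2 (at least 1602-fold lower), CDA (at least 1445-fold), PPP1R14A (at least 1058-fold), HSPB8 (at least 919-fold), AKR1C1 (294-fold), ZNF880 (266-fold), MFAP5 (204-fold), MISP (191-fold), TNNC1 (166-fold), LINC00707 (136-fold), ZNF93 (90.9-fold) and ZNF540 (77.9-fold). MISP, with its resistant reads in 1.39% of cells, ran from -11.27 to -6.52 in log2 ratio.

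Resistant DU145 cells had lower levels of cell cycle genes and tubulins. The lists for spindle checkpoint and mitosis (median log2 ratio -1.79, 22 of 25 members at least 2-fold lower), G2M phase (-1.59, 41 of 52), tubulins (-1.51, 9 of 13) and S phase (-1.07, 25 of 44) lay below the central 95% of expression-matched random lists. PLK1 stood at 242.7 CPM in sensitive and 24.4 CPM in resistant cells, CDC20 at 755.5 and 122.1 CPM, TUBA1B at 1006 and 246 CPM, and TUBB4B at 940.8 and 237.7 CPM, with reads among tubulin paralogs not separable here. Also lower were heat shock genes (-1.10, 9 of 13) and the epithelial list (-1.06, 9 of 17, but 3 at least 2-fold higher). So were NRF2 targets (-0.86, 10 of 23, but 1 higher) and the ATF4 stress response (-0.76, 6 of 24, but 2 higher). The ATF4 median was -0.39 and no longer apart in even-numbered cells. KRT8 stood at 956.0 and 20.9 CPM, DNAJB1 at 360.2 and 83.8 CPM, ABCC2 at 91.5 and 4.13 CPM and SLC7A5 at 61.6 and 9.44 CPM.

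Cholesterol synthesis genes had the next highest median after 7q21 in DU145 among lists with over 3 measured members, at a log2 ratio of 1.43 with 15 of 23 members at least 2-fold higher. INSIG1 stood at 16.3 and 159.7 CPM, MSMO1 at 50.9 and 302.3 CPM, and CYP51A1, which lies inside the 7q21 run, at 72.8 and 516.6 CPM. The mesenchymal list (0.90, 9 of 18), the basal and stem-like list (0.77, 3 of 8), MHC class I presentation (0.53, 6 of 13), glycolysis and hypoxia (0.27, 5 of 28, but SLC2A3 30.2-fold lower, and 0.10 and no longer apart in even-numbered cells) and ribosomal proteins (0.11, 0 of 62) were apart on the higher side too. So were the 3 measured members of the list of keratins and squamous differentiation (1.98), which was 0.67 and not apart as the mean of per-cell CPM. LOXL2 stood at 29.6 and 138.5 CPM, CD44 at 94.0 and 223.1 CPM, PSMB8 at 23 and 111.6 CPM and KRT80 at 19.3 and 90.1 CPM. Of the 32 lists with at least 3 measured members, 16 did not stand apart in DU145.

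**Figure D3:**
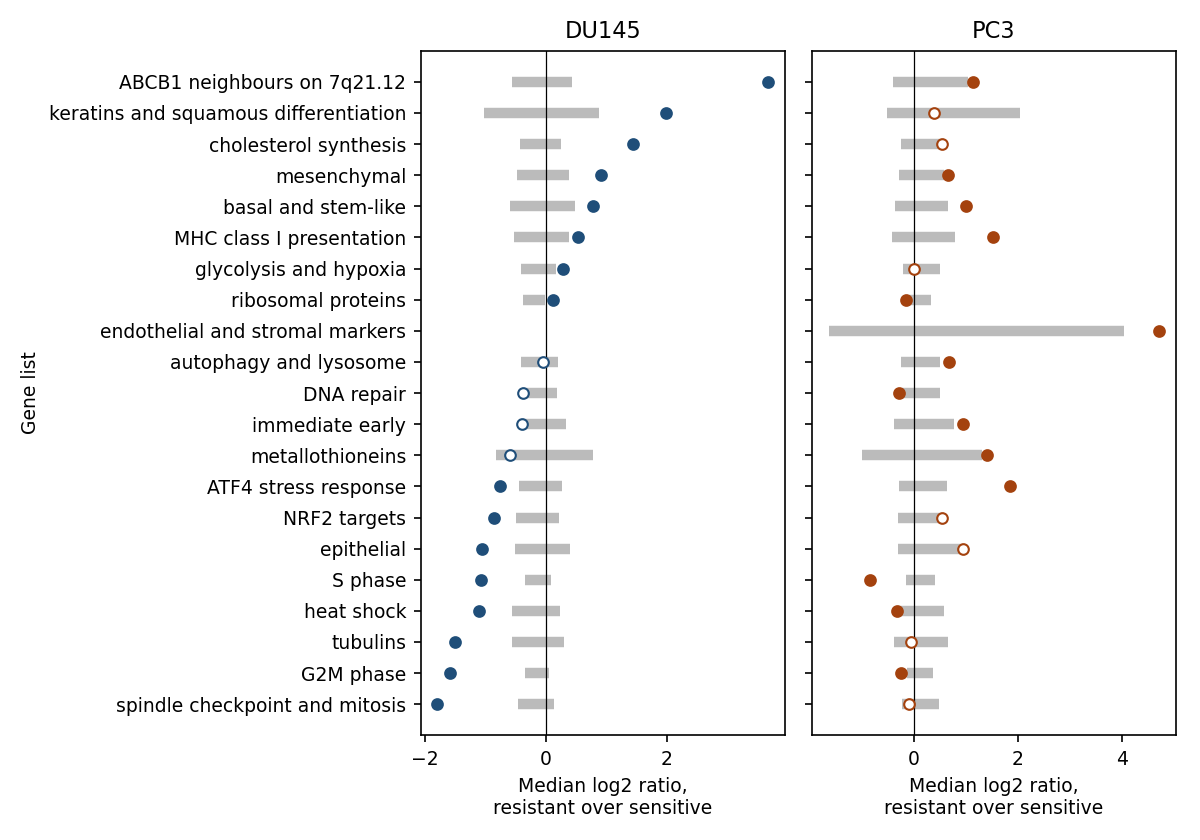
Median log2 ratio of each list that stood apart in either line, with the central 95% of matched random lists as grey bars. Filled points stand apart and open points do not.

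In PC3, 1895 genes were at least 2-fold higher and 903 at least 2-fold lower in resistant cells, among 9529, so 67.7% were higher. Scaling by total counts alone moves the median by -0.20 and gives 1470 higher and 1323 lower, 52.6% higher. Most genes at the top had 0 reads over the 90 sensitive cells. TCN1 was at least 119440-fold higher, at 2119 CPM and read in 100% of resistant cells, KRT75 at least 27095-fold, GJB2 at least 9672-fold, CCND2 at least 8543-fold, ARHGDIB at least 8423-fold, NOG at least 6368-fold, DSP at least 5408-fold, BCL2A1 at least 4934-fold, SLC1A3 at least 4198-fold, TRBC2 at least 3492-fold and ADGRL2 at least 3460-fold. IL1RL1, with 1 read against 59472, was 54385-fold higher (9761 to 2148130). On the other side, HTATIP2 was at least 5756-fold lower, SDHAF3 at least 3285-fold, GALC at least 1821-fold, ZNF239 at least 1433-fold, HIKESHI at least 1325-fold, EED at least 1217-fold, SLITRK4 at least 981-fold, PICALM at least 919-fold and ZNF32 at least 861-fold. NID1 was 4368-fold lower from 3994 reads against 1 (783 to 172553), LXN 2138-fold from 7820 against 4, and LRRC38 1938-fold from 3545 against 2 (536 to 16011).

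Among lists with over 3 measured members that stood apart in PC3, the ATF4 stress response had the highest median, a log2 ratio of 1.85 with 18 of 23 members at least 2-fold higher. CHAC1 stood at 0.781 and 63.4 CPM, ATF3 at 0.680 and 14.1 CPM and SESN2 at 0.680 and 12 CPM. MHC class I presentation had a median of 1.53 (8 of 12, ERAP2 at 1.19 and 51.5 CPM, HLA-C at 16.1 and 72.1 CPM), the basal and stem-like list 1.01 (7 of 13, ITGA2 at 13.9 and 264.3 CPM) and the autophagy and lysosome list 0.67 (6 of 25, MAP1LC3B at 119.8 and 546.4 CPM, but 0.46 and not apart in odd-numbered cells). The mesenchymal list had a median of 0.66 (11 of 25, not apart under 2 alternatives, at 0.62 without each gene's top cell), with CDH11 at 9.35 and 247.1 CPM and SPARC at 55.3 and 3.70 CPM, the order reversed against sensitive cells high in ribosomal protein reads (log2 ratio 2.10), and the immediate early list 0.94 (7 of 16, not apart under 3 alternatives, at 0.67 in odd-numbered cells), with KLF6 at 45 and 197.6 CPM. The 3 measured metallothioneins (1.41) and the 3 measured endothelial and stromal markers (4.72, PECAM1 at 2.31 and 60.9 CPM) were apart too, but not under 5 and 2 of the 17 alternatives. On the lower side were S phase (-0.83, 17 of 44, CLSPN at 123.8 and 26.2 CPM), heat shock (-0.32, not apart under 7 alternatives), DNA repair (-0.28, not apart under 5), G2M phase (-0.24, but 0.066 in even-numbered cells) and ribosomal proteins (-0.14, but 0.38 against sensitive cells low in ribosomal protein reads). Of these lists, S phase alone stood apart under all 17 alternatives. Of 33 lists with at least 3 measured members, 19 did not stand apart in PC3, among them tubulins (-0.05) and spindle checkpoint and mitosis (-0.10, 4 of 25 members at least 2-fold higher and 2 lower). PLK1, lower in DU145, was higher in resistant PC3 cells, at 35.4 and 99.5 CPM (log2 ratio from 0.87 to 2.61 over the alternatives), as was UBE2C at 135.5 and 375.2 CPM (1.11 to 1.70). UBE2C lies in a run of 10 consecutive genes at least 2-fold higher in PC3, on chromosome 20 from SYS1 to CTSA.

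Cells scored above 0 for neither S nor G2M genes were more frequent in both resistant groups. At equal depth they made up 3 of 59 sensitive (5.08%, 1.06 to 14.1%) and 39 of 69 resistant DU145 cells (56.5%, 44 to 68.4%), and 11 of 77 sensitive (14.3%, 7.35 to 24.1%) and 52 of 87 resistant PC3 cells (59.8%, 48.7 to 70.1%). Cells assigned to S made up 37.3%, 21.7%, 49.4% and 16.1% of sensitive DU145, resistant DU145, sensitive PC3 and resistant PC3 cells, and cells assigned to G2M 57.6%, 21.7%, 36.4% and 24.1%. Scores were set within each line, so they rank cells against the other state of the same line and give no proliferation rate.

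**Figure D4:**
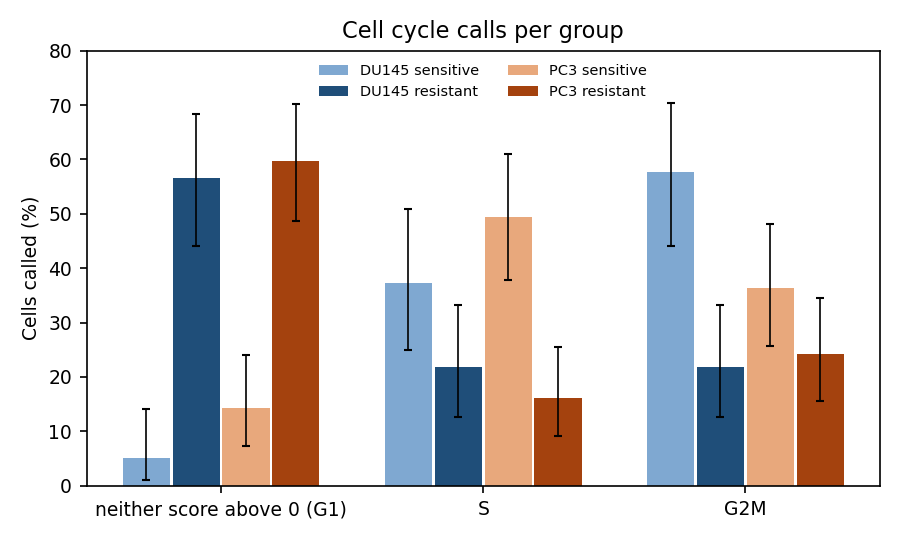
Shares of cells per assigned phase in the 4 groups at 1000000 reads per cell, with exact binomial intervals. Scores were set within each line.

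Across genes, the ratios of the lines were only weakly related (Pearson's r 0.107, Spearman's rho 0.0931, 10529 genes, same sign in 51.8%), and genes are not independent replicates. Of 8217 genes that met the level rule in both lines, 203 were at least 2-fold higher in both, where independence gives 110.2, and 105 at least 2-fold lower in both, where it gives 62.1. Another 56 were higher in DU145 and lower in PC3, from 666 and 643 genes, and 134 the reverse, from 793 and 1360. These opposite counts were not set against independence, so they are not read as a divergence of the lines. After ABCB1, the genes furthest on the higher side in both lines were STC1, RTN1, MPZL2, IL31RA, RGS17, GBP2, ISG20, ERAP2 and ARG2, with DU145 log2 ratios from 5.53 for STC1 to 2.70 for ARG2. IL31RA was 17.1-fold higher in DU145 and 22.6-fold in PC3, though its log2 ratio ran from 3.06 to 8.79 and from 3.23 to 8.05 over the alternatives, RGS17 15.1-fold and 12.4-fold, and ISG20 7.67-fold and 10.1-fold. Lower in both were ZNF91, ZNF675, TMEM131L, MCM10, LPAR2, AGAP3, RRM1, RPP25, BLM and DTL. Of these RRM1 was 3.10-fold lower in DU145 and 3.33-fold in PC3, and MCM10 3.52-fold and 4.97-fold.

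**Figure D5:**
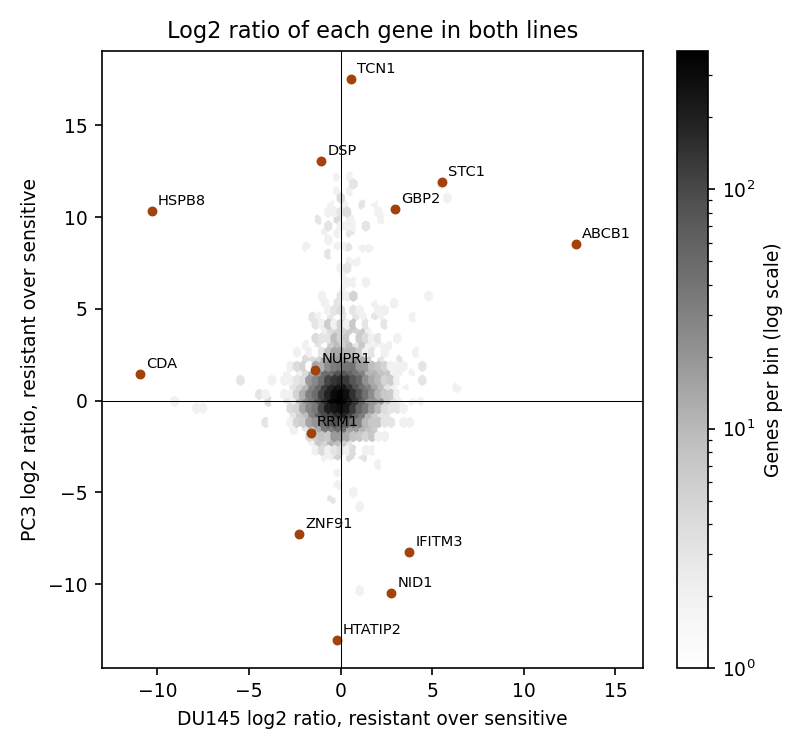
Log2 ratio of each gene in DU145 and PC3, resistant over sensitive. Labelled points are among the named genes, and those with 0 reads in a group have a fitted ratio that is no bound.

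A test with the lines as the replicates, 2 against 2 with 1 residual degree of freedom, asked which genes move alike. With edgeR, 0 genes were higher and 0 lower at an adjusted p of 0.05 among 24672, while 1084 had an unadjusted p under 0.05, where chance alone gives 1234. DESeq2 on the same sums called 391 higher and 66 lower. It ran on 40404 genes, without the filter on low counts applied for edgeR, and 23170 of them had an adjusted p. The DESeq2 test was not run on simulated data, so its error rate here is not known. ABCB1, higher in 2 of 2 lines, had a log2 fold of 10.94 (SE 1.53) and an adjusted p of 1 with edgeR, and a log2 fold of 10.95 (SE 1.09) and an adjusted p of 2.21e-19 with DESeq2. NUPR1 had a log2 fold of 0.15 (SE 0.97), an adjusted p of 1 with edgeR and of 1.00 with DESeq2. With edgeR adjusted over the list alone, ABCB1 and ABCB4 passed among 13 drug transporters (smallest adjusted p 0.0143) and BCL2A1 among 12 anti-apoptotic genes (0.00412), each higher in 2 of 2 lines, without correction for the number of lists. ABCB4 lies beside ABCB1 in the raised 7q21 segment, with 1 read in sensitive and 545 in resistant DU145 cells. Its reads may not be separable from those of ABCB1 here, so the 2 transporters are not independent. IL1B passed among 23 NF-kB targets and cytokines (edgeR adjusted p 0.0424), but it had 0 reads in both DU145 groups, so its difference, 58.4-fold higher at 1228 against 21 CPM, is that of PC3 alone.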

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

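The test of NUPR1 without cells under 9000 detected genes, the values by depth and gene number together, the GC correction, the genes of the segment free of overlap and the order of sensitive PC3 cells by ribosomal protein reads were chosen after the results they concern were seen. The other tests in this part, with their bounds, were set down before their own values were computed. Those on the segment around ABCB1 and on the genes absent from a PC3 state still came after these patterns were seen.

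NUPR1 had a log2 ratio 3.07 higher in PC3 than in DU145, with opposite signs in the lines (1.69 and -1.37 as fitted), a difference that was not tested, since each line has 1 sum per state. In DU145 the lower value may come from a few sensitive cells: without the 8 cells under 9000 detected genes the log2 ratio was -0.19. A difference in depth cannot be told apart from this, because thinning to equal depth gave 0.10, a value set beforehand as pointing to depth, but the same cells without thinning gave -0.17, so leaving out shallow cells moved the ratio most and thinning then turned its sign. Of those 8 cells 7 were also under 1000000 reads and held all 616 NUPR1 reads of the 8, whereas leaving out the 5 shallow sensitive cells with more genes left the ratio at -1.38. Whether those 7 are stressed, dying or poorly captured cells was not tested, and in PC3 the ratio stayed between 1.21 and 2.18 under the 17 alternatives.

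Opposite directions also set apart 6 other genes, none with a test of the difference. The log2 ratio in PC3 less that in DU145 was at least 19.51 for HSPB8 (0 reads in resistant DU145 and in sensitive PC3 cells), at least 13.46 for DSP, at least 11.95 for CDA, 14.13 for TRIM36, -14.86 for NID1 and -12.00 for IFITM3. TRIM36 and NID1 each rest on 1 read in a PC3 group. IFITM3 stood at 258.0 CPM in sensitive and 0.844 CPM in resistant PC3 cells, and at 1.00 and 13.5 CPM in DU145, and its reads are not separable from those of close paralogs here.

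Lists that stood apart on opposite sides were the ATF4 stress response and ribosomal proteins. The median ratio of resistant over sensitive cells in PC3 less that in DU145 was 2.62 in log2 for the first and -0.25 for the second. Neither difference was tested. The ATF4 list was lower in sensitive PC3 than in sensitive DU145 cells, at a median log2 ratio of -2.39 (18 of 24 members at least 2-fold lower, 1 higher). In DU145 the ATF4 list no longer stood apart in even-numbered cells. The ribosomal protein value depends on which sensitive PC3 cells are used, as 39 of the 90 had a median of 3.12% of reads on these genes and 51 a median of 1.63%. The 39 cells also had fewer detected genes (median 9714 against 11459) and fewer reads (median 1537950 against 1828130) than the 51. In order of cell number these kinds made 16 runs, where 10000 shuffles gave a median of 45 and a lowest of 27. Such an order can follow the capture positions, plates or a second culture, none of which the labels name, and the cells were divided by the measure itself, so no cause was tested.

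The run of higher genes around ABCB1 in resistant DU145 cells was weighed as the second pattern. GC content is argued against as its cause: less the GC trend the neighbours kept a median log2 ratio of 3.64. A gain of copies of the whole segment cannot be told: of 20 genes in it too low to define it 17, or 85%, were higher in resistant cells, past the bound set beforehand, but 10 of the 20 overlap genes at 10 CPM or more whose reads they may share, and of the other 10 genes 8, or 80% with an interval from 44.4%, were higher, against 55.7% of 8853 such genes elsewhere. Among those 8 genes are STEAP4, also a measured member of the neighbour list, and ABCB4, whose reads may not be separable from those of ABCB1. Regulation of the whole region without a gain was not tested and stays open, since expression alone does not count copies. The segment was found in these data, so a gain remains a hypothesis.

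The third pattern is genes read in one PC3 state and absent, at 3 reads or fewer, from the other: among genes at 10 CPM or more and in at least 25% of cells where present, 121 were read in resistant cells alone and 11 in sensitive cells alone, against 3 and 4 in DU145. That the cells labelled resistant PC3 come from another line is left open by the set test: of 16 genes at 50 CPM or more in DU145 and absent from sensitive PC3 cells, 10 were absent from resistant cells too, 62.5% (35.4 to 84.8%), between the bounds set beforehand, and low CTNNA1 is shared by both PC3 states. This test cannot decide, because CADM1, EFEMP1, CHD7 and CRNDE, read in resistant cells, also belong to the 121 genes of the pattern. Of the absent genes, RPS4Y1, DDX3Y and EIF1AY all lie on chromosome Y, so the interval treats linked genes as independent. Loss of short segments around PICALM, EED, HIKESHI, ZNF239 and ZNF32 could account for the absent genes, but the planned share, 2 of 12 neighbours within 500000 bases or 16.7%, lay between the bounds. Those 2 are ZNF485, between ZNF239 and ZNF32, at 1 read, and ME3, next to HIKESHI, at 0, while PRSS23 beyond ME3 had 69 reads against 8341 and the others lie outside these stretches, so the loss stays open. Selection of a clone that differed before treatment was not tested and stays open.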

How the results depend on the processing

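Tests chosen after the data were seen are those on cells with at least 9000 genes, on cells with at least 1000000 reads without thinning, on sensitive PC3 cells low or high in ribosomal protein reads, on ratios less their GC trend and on genes at 10 CPM or more.

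Of 120 counts of 2-fold genes under 20 alternatives, 109 stayed within 1.5 times the reported count. Within that limit PC3 depended on which sensitive cells were used. Those high in ribosomal protein reads gave 2608 higher and 1183 lower, and those low in such reads 1968 higher and 829 lower. Of the 903 lower genes reported, 637 (70.5%) stayed so against the low ones. A level rule of 50 CPM gave 276 higher and 522 lower in DU145 and 811 higher and 334 lower in PC3, and a rule of 2 CPM gave 1613 higher in DU145 and 1402 lower in PC3, since fewer or more genes then qualify. The other moved counts concern sensitive PC3 against sensitive DU145 cells, where total counts turn the balance to 53.9% higher. In DU145 the share of 2-fold genes on the higher side passed 50% with total counts (61%), without each gene's top cell (57.6%), in odd-numbered cells (56.1%), at 2 CPM (52.7%), with the mean of per-cell CPM (51.9%) and less the GC trend (51.2%), and the cause was not tested. Pearson's r across genes ran from 0.0794, against sensitive PC3 cells high in ribosomal protein reads, to 0.121, with 0.081 in odd-numbered cells, the cause not tested.

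Across lines edgeR called 0 genes under each of its 6 alternatives, with 478 to 1745 unadjusted p under 0.05, and DESeq2 called 391 higher and 66 lower. The cause of the gap was not tested. No paired analysis was possible because the replicate numbers count cells within a group and pair no cell of one group with a cell of another. Leaving out a line leaves 1 sum against 1, which has no residual degree of freedom.

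Of 1105 list medians under 17 alternatives, 1021 stayed within the bounds or on the same side of them, 33 no longer stood apart and 49 newly did. Direction was compared only for lists that stood apart as reported. Of these, 2 medians reversed: G2M phase in PC3 at 0.066 in even-numbered cells, and ribosomal proteins in PC3 at 0.38 against sensitive cells low in such reads. The neighbours of ABCB1 in DU145 ran from 3.56 to 3.96, cholesterol synthesis in DU145 from 1.40 to 1.65, S phase from -1.23 to -0.68 in DU145 and from -1.14 to -0.49 in PC3, and the ATF4 stress response in PC3 from 1.66 to 2.06. Of 4675 values of named genes, 2981 stayed within their counting interval and 1691 moved out of it. Among genes with a reported ratio of at least 2-fold, a limit set after the values were seen, 3 values reversed: NUPR1 in DU145 at 0.10 after thinning, ATF3 in DU145 at 0.70 in even-numbered cells and SPARC in PC3 at 2.10 against sensitive cells high in ribosomal protein reads. The cause was not tested for ATF3 and SPARC. NUPR1 in DU145 ran from -3.40, as the mean of per-cell CPM, to 0.10. The 24 phase shares stayed within their intervals, and 13 of 64 shares of cells with a gene did not: 9 at a demand of 5 reads, 2 without thinning and 2 at a lower thinning depth, each of which changes what can be detected. At 1000000 reads per cell, a gene of about 1 CPM is read by chance, which limits NUPR1 in DU145.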

Other observations

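The windows of 15 genes and the list members follow rules set beforehand, no test was run in this part, and which list members to print was chosen after their values were seen.

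The lowest windows in DU145 were on chromosome 10 from 4963253 to 7787993 (AKR1C1 to KIN, median log2 ratio -1.89, 13 of 15 genes at least 2-fold lower), on chromosome 7 from 66205317 to 73770270 (TPST1 to CLDN3, -1.69, 13 of 15) and on chromosome 19 from 19623655 to 23395471 (LPAR2 to ZNF91, -1.61, 11 of 15). In PC3 the highest were on chromosome 5 from 43444252 to 55022671 (TMEM267 to ESM1, 2.61, 10 of 15) and from 145471799 to 149354583 (PRELID2 to GRPEL2, 2.42, 11 of 15), and on chromosome 20 from 44531785 to 45811427 (PKIG to DNTTIP1, 2.22, 9 of 15). The lowest were on chromosome 11 from 303655 to 812880 (IFITM2 to RPLP2, -1.86, 9 of 15), which holds IFITM3, on chromosome 19 from 19320829 to 24129968 (MAU2 to ZNF254, -1.56, 9 of 15) and on chromosome 12 from 102073103 to 105074197 (NUP37 to NOPCHAP1, -1.46, 11 of 15). LPAR2, ATP13A1, ZNF14, ZNF430, ZNF714, ZNF431 and ZNF91 were in a lowest window of both lines, which was not tested.

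Several genes had large ratios in a line where their list did not stand apart. In DU145, TNF stood at 41.4 CPM in sensitive cells, read in 14.1% of them, and at 0 reads in resistant cells, at least 2673-fold lower, a difference that rests on few cells, with a log2 ratio from -13.85 to -2.69 over 17 alternatives, and ICAM1 at 33.6 and 2.05 CPM. In PC3, CDKN1A stood at 2.49 and 69.6 CPM in sensitive and resistant cells, TNFAIP3 at 0.0177 and 9.35 CPM, STARD4 at 0.822 and 93 CPM and SLC2A3 at 0.136 and 14.8 CPM. Over the alternatives their log2 ratios ran from 4.0 to 6.59, from 7.61 to 9.65, from 5.98 to 12.80 and from 5.91 to 7.91. ESRP1 was at least 928-fold and S100A9 at least 1551-fold higher in resistant PC3 cells, from 0 reads in sensitive ones. The epithelial list, which holds ESRP1, lay just inside the bound in PC3, at a median log2 ratio of 0.94164 against 0.94185 (percentile 97.49). SLC2A3 lay the other way in DU145, at 217.2 and 7.19 CPM, where its list stood apart on the higher side, a difference between lines that was not tested. No immune cell or red cell marker of the lists reached 5 CPM in a group.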
